A study of Mus musculus with 4 samples.

How the data were processed

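Total RNA was extracted from whole retinas with Sepazol and libraries were made with an Illumina mRNA-seq kit, per the labels' protocols. Of the 4 libraries, each is a group of its own: control (R26R-DTA without Cre) and DTA (Msi1-CreERT2 with R26R-DTA), at day 1 and day 5 after injury. The number of mice per library is not given in the sources used here.

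The deposited values are FPKM per gene, computed by the authors before deposit. The submitters' processing notes name CASAVA 1.8.2, bcl2fastq 1.8.4 and Cufflinks 2.1.1 and the mouse build mm9, without roles or order. The aligner and the annotation are not given in the sources used here. Per the file headers, each gene has an FPKM, lower and upper bounds and a status. FPKM divides by transcript length and by the fragments of the library, so a change in a few very abundant transcripts moves all others; rod transcripts are such a case in the retina. The control files and the day 5 DTA file hold 23021 lines for 22558 gene symbols. The day 1 DTA file holds 5847 lines for 5799 symbols, from chromosomes 1 (1279 lines), 10 (1054), 11 (1704), 12 (738), 13 (821 and 7 unplaced) and 14 (244, up to position 41780096). Its FPKM are used as deposited, on the assumption that they were normalised over the whole library before the lines were taken out. Over the genes shared by all 4 files the FPKM sums were 100232, 101093, 93502 and 101950 in the order day 1 control, day 1 DTA, day 5 control and day 5 DTA.

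Lines with status FAIL (25, 10, 7 and 13 in the same order) or HIDATA (1, 0, 1 and 0) are listed at 0 in the files and were read as missing; Per1 in day 5 DTA and Stat3 in both DTA libraries are among them. Lines of low data status (283, 40, 283 and 283) were used as listed. Line order differs between files, so genes were joined on symbol, after the FPKM of the 251 symbols with several loci were summed. Locus starts in the files count from 0, since 10368 of 22088 loci match the reference annotation's start after adding 1 and 656 match without, so printed starts have 1 added.

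The files hold no fragment counts. The depth was estimated from the most common low value of FPKM times transcript length, which was assumed to be 1 fragment. Only genes with 1 annotated transcript of more than 1500 bases were used, 414, 98, 331 and 256 in the same order. Estimates were 73.3 M, 98.8 M, 35.6 M and 28.8 M fragments, slightly low because effective lengths are shorter than annotated ones. One fragment on a transcript of 1 kilobase is then worth 0.0136, 0.0101, 0.0281 and 0.0348 FPKM. In 17.8%, 23.8%, 10.3% and 10.6% of lines the upper bound lies below the FPKM itself. The bounds were therefore used only in one alternative, for the median half-width and for the noise of the simulated libraries. These intervals hold no spread between mice.

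Differences were taken on log2(FPKM + 1). Since each group has 1 library, no test across samples was made and no p-value is given for a gene, a list or a count. A gene was called higher or lower when the difference was at least 1 in size, the FPKM at least 5 in one of the 2 libraries and, for DTA against control, the difference larger in size than the gene's difference between the 2 controls. A gene without an estimate in one control was not called, which left out 0 genes at day 1 and 1 (Srsf5) at day 5. For the difference between the days, the same sizes were asked of the day 5 difference minus the day 1 difference.

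The size rule, the gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. There were 32 lists with 521 distinct genes, of which 511 are in the files and 137 in the day 1 DTA file: 14 of cell types (rods, cones, Müller glia, bipolar, amacrine, horizontal and ganglion cells, microglia, other leukocytes, endothelium, pigment epithelium, lens, red blood cells, and cornea with iris, muscle and connective tissue), 15 of processes (gliosis, interleukin-6 family, chemokines, phagocytes, complement, interferon, p53, integrated stress response, immediate early genes, heat shock, cell cycle, progenitor factors, matrix, EGF receptor and the diphtheria toxin pathway) and 3 technical ones (clock, sex-linked and housekeeping genes). Some genes stand in more than 1 list. Each list was described by its members higher and lower, its median difference over every measured member with no floor, and the percentile of that median among 10000 random lists of the same size drawn from 20 bins of mean log2(FPKM + 1), seed 20240501, for lists of at least 3 measured genes. Genes are not independent replicates, so a percentile describes a list within the libraries compared and is not a p-value.

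Named were the 10 largest differences each way per day, 5 each way between days, up to 4 members per list with FPKM of at least 1 in one library, and a few genes fixed by name, among them Msi1, Gfap, Edn2, Lif and Eef2. Some genes that the rule takes are not reported here. Symbols that are clone or model names and small RNA genes were left out, 730 small RNA symbols in all. A few further prefixes of both kinds were added to this after the data were seen. Without that, AF357355 (7.60) and Scarna10 (5.72) would stand among the largest at day 5, and AF357355 (7.02) and Bc1 (-5.01) among the differences between days. Genes printed beyond these rules serve as examples from a list and were chosen after their values were seen.

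Alternatives were pseudocounts of 0.1 and 5, floors of 1 and 10 FPKM or none, rescaling to the same sum per library (TPM), by the median ratio to the geometric mean, or to the same sum without photoreceptor markers and the 50 most abundant genes, non-overlapping intervals, the highest locus per symbol, the control of the other day, the mean of both controls and no requirement on the controls. Rescaling used genes in all 4 files for day 1 and in the 3 full files for day 5, and factors were set relative to the day 1 control for both sums and centred on the geometric mean for the median ratio, so that floor and pseudocount stay close to the FPKM scale. Floors of 1 and none give the same counts, since a difference of 1 at pseudocount 1 needs an FPKM of at least 1. Alternatives added after the data were seen were reading FAIL and HIDATA as 0, leaving out small RNA genes, leaving out lens and pigment epithelium markers, using at day 5 only genes of the day 1 file, and list members at 5 FPKM or more.

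The call was tested on simulated libraries with known folds for 50 genes of each fold. At day 1 (5785 genes) 100% of 3-fold, 6-fold and 1/3-fold genes and 98% of 1/6-fold genes were called, and 0.0537% of 5585 unchanged ones. At day 5 (22541 genes) 98% of 1/3-fold and 100% of 3-fold, 6-fold and 1/6-fold genes were called, and 0.0358% of 22341 unchanged ones. The noise was taken from the deposited bounds of the control libraries, part of which lie below the FPKM, so these shares depend on those bounds. They do not cover the spread between mice. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.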

Results

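The data are RNA-seq gene expression values from whole retinas of mice of about 8 weeks on a mixed C57BL/6 and 129 background. The injured mice carried Msi1-CreERT2 and R26R-DTA. CreERT2 is a Cre recombinase that is active only when a ligand is bound to its estrogen receptor part, and R26R-DTA is an allele that produces diphtheria toxin fragment A (DTA) in cells where Cre has acted. The toxin inactivates elongation factor 2 and stops protein synthesis, which kills the cell. Control mice carried R26R-DTA without Cre. There were 4 libraries, 1 per group: control and DTA at day 1 after injury, and control and DTA at day 5. Values are FPKM (fragments per kilobase of transcript, scaled to the fragments of the library) on the mouse build mm9. Differences are DTA minus control of log2(FPKM + 1), and folds are ratios of FPKM, given only where both values are at least 1.

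With 1 library per group there are no replicates, no standard deviations and no p-values for any gene, so a gene is called higher or lower by size alone. The difference had to be at least 1 on the log2 scale, the FPKM at least 5 in one of the libraries, and the difference larger than that gene's own difference between the 2 controls. Low FPKM values, read as single fragments, put the depth at about 73.3 M (mega) fragments for the day 1 control and 98.8 M fragments for day 1 DTA. For the day 5 control and day 5 DTA the depth was about 35.6 M fragments and 28.8 M fragments. The authors' confidence intervals had a median half-width of 4.62%, 3.74%, 6.39% and 6.84% of the FPKM in the same order, over genes at 5 FPKM or more. These intervals cover counting and assignment of fragments in one library and not the spread between mice. The day 1 DTA file holds 5799 of the 22558 gene symbols, those on chromosomes 1, 10, 11, 12 and 13 and the first part of 14, so the day 1 comparison covers those genes.

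The control libraries set the background. Among the fixed lists they differed in transcripts of the lens and of the retinal pigment epithelium, tissues that adjoin the retina, and by number most of the genes that differed were small RNA genes. Of 19 lens markers, 18 were lower in the day 5 control than in the day 1 control, with a median difference of -2.85. Cryaa, which encodes alpha A crystallin, stood at 604 FPKM in the day 1 control and 105 in the day 5 control. Of 13 pigment epithelium and melanocyte markers 5 were lower, with a median of -1.09, and Rpe65, the visual cycle isomerase, stood at 16.0 and 2.69 FPKM. Of 5 red blood cell markers 2 were lower, with a median of -1.23.

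Sex-linked transcripts also set the controls apart. Xist, the RNA that coats the inactive X chromosome, stood at 0.00596 FPKM in the day 1 control, 53.7 in the day 5 control and 60.4 in day 5 DTA. Ddx3y, a Y-linked gene, stood at 15.6, 0.175 and 0.275 FPKM. The day 1 DTA file holds neither chromosome X nor Y. At day 5 the 5 sex-linked genes had a median difference of 0.02 between DTA and control, and none was called; against the day 1 control it was -2.63. Between the controls 2 immediate early genes were lower at day 5, among them Egr1 at 36.0 and 7.75 FPKM, 1 matrix gene was lower and 1 endothelial gene was higher. In the other 25 of the 32 fixed lists no member was called between the controls. Some of these lists still differed. All 17 Müller glia markers were below 0 (day 5 minus day 1, median -0.38, percentile 0). Of 14 bipolar markers 13 were below 0 (median -0.30, percentile 0.06). Over all 9321 genes at 5 FPKM or more, 80 were higher and 160 lower in the day 5 control, of which 70 and 92 were small RNA genes.

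At day 1 the question is which transcripts differ in the retina soon after the toxin is induced. Some genes of the interferon, chemokine and reactive gliosis lists stood higher in DTA, while the medians of the rod, cone and microglia markers lay close to the control. Gadd45b, a stress-induced regulator of growth arrest and MAP kinase signalling (chromosome 10, 80392836 to 80394949), stood at 3.56 FPKM in control and 54.0 in DTA, 15.2-fold higher. Irf1, a transcription factor of the interferon response (chromosome 11, 53583516 to 53591876), stood at 1.52 and 27.5 FPKM, 18.2-fold higher. Gfap, the intermediate filament of reactive glia (chromosome 11, 102748650 to 102758514), stood at 4.66 and 20.7 FPKM, 4.43-fold higher.

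The remaining genes with the largest positive differences at day 1 were Ccl2 (3.22) and Ccl5 (2.51), chemokines that attract monocytes and T cells; Socs3 (3.08), the feedback inhibitor of JAK and STAT signalling; Rsad2 (2.28), an interferon-induced antiviral enzyme; Serpina3n (2.26), a protease inhibitor of reactive astrocytes; Nuak2 (1.94), a stress-responsive kinase; and Nr1d1 (1.89), the clock repressor REV-ERB alpha. Ccl2 was listed at 0 in both controls and at 8.32 FPKM in day 1 DTA.

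By list, all 3 measured reactive gliosis genes were higher, with a median of 2.26, at percentile 99.985 of 10000 random lists of the same size and expression level. Of 5 interferon and antigen presentation genes 2 were higher (median 0.95, percentile 100), with Stat2 at 0.47. Of 8 chemokines and cytokines 2 were higher (median 0.83, percentile 100), with Ccl12 at 1.64 and Ccl7 at 1.04 under the floor of 5 FPKM. Of 4 interleukin-6 family and survival factor genes 1, Socs3, was higher (median 0.85, percentile 99.99), and it also stands in the reactive gliosis list. Lif, the cytokine leukemia inhibitory factor, stood at 0.206 FPKM in control and 1.93 in DTA, a difference of 1.28 under the floor. Of 4 immediate early genes 1, Fos (1.64), was higher (median 1.21, percentile 99.98), and Egr2 differed by 2.30 under the floor. Of 4 integrated stress response genes 1, Atf3 (1.47), was higher (median 0.14, percentile 88.8, -0.10 over members at 10 FPKM or more). No member of the p53 and cell death list was called (5 measured, median 0.23, percentile 96.8), with Ripk1 at 0.78 and Phlda3 at 0.76. Clock genes lay higher as a list: of 7 measured, Nr1d1 and Per1 (1.32) were higher, Cry1 stood at 0.95 and Npas2 at 0.85, and the median was 0.85 (percentile 100). With a pseudocount of 5 the differences of Atf3 (0.85) and Rsad2 (0.94) lay under the size rule, and against the day 5 control those of Atf3 (0.95) and Per1 (0.96) did.

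Photoreceptor lists were close to control at day 1. None of 10 rod markers was called (median 0.04, percentile 78.5, a sign that turned to -0.02 after scaling by the median ratio and to -0.03 after scaling to the sum without photoreceptor and abundant genes). Sag, rod arrestin, stood at 1149 and 1412 FPKM, and Reep6, a protein of rod membrane trafficking, at 473 and 296. None of 4 cone markers was called (median 0.12, percentile 79.9), with Thrb at 0.20 and Cnga3 at 0.15. Of 6 Müller glia markers 1, the transcription factor Sox9 (1.05), was higher (median -0.10, percentile 7.35), a call that ended with a pseudocount of 5 (0.74) and with the sum without photoreceptor and abundant genes (0.99), and glutamine synthetase, Glul, stood at 1044 and 550.0 FPKM, a difference of -0.92. Inner retinal markers had no call: bipolar (6 measured, median -0.08, percentile 5.72, Isl1 at -0.33), amacrine (2, 0.11), horizontal (3, -0.28, percentile 1.25, Sept4 at -0.33) and ganglion cells (2, -0.24, Nefh at -0.39). Against the day 5 control the medians of 4 of these lists with at least 3 measured genes turned, to 0.23 for bipolar cells, 0.0157 for Müller glia, -0.00442 for rods and -0.000361 for cones. The 2 amacrine markers turned as well, Slc18a3 to -0.32 and Chat to -0.03. None of 5 microglial markers was called (median 0.01, percentile 40.2), with Cd68 at 0.56 and Fcer1g at 0.11.

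Among tissues that dissection can carry along, the 10 lens markers had a median of 1.19 (percentile 100) with Cryga at 2.14 and Crygf at 1.83. None was called, since each differed more between the controls. The 3 pigment epithelium markers had a median of -0.71 (percentile 0.005), with Pmel at -0.95 and Rgr at -0.71. Against the day 5 control their median was 1.03. The 2 red blood cell markers had a median of 0.48, the 8 markers of cornea, iris, muscle and connective tissue -0.02 (percentile 7.12, 0.0307 against the day 5 control), and the 2 endothelial markers 0.55, with Rgs5 at 0.88. Both endothelial markers turned against the day 5 control, Rgs5 to -0.28 and Pecam1 to -0.19. No member of the leukocyte or sex-linked lists is in the day 1 DTA file.

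The other lists held no called gene at day 1. Medians were 0.26 for activated phagocytes (1 gene, Cd63), -0.22 for complement (2 genes), 0.26 for heat shock and oxidative stress (2 genes, Txnrd1 at 0.58), -0.02 for cell cycle (8 genes, percentile 4.91, Mcm6 at 0.25), 0.12 for progenitor and neurogenic factors (6 genes, percentile 88.5, -0.19 over members at 1 FPKM or more, Six6 at -0.19), 0.07 for extracellular matrix (5 genes, percentile 68.7, Ctgf at 0.97), 0.13 for EGF receptor ligands and receptors (4 genes, percentile 87.3, Egfr at 0.45), -0.02 for the diphtheria toxin target pathway (3 genes, percentile 33.4) and 0.16 for housekeeping genes (3 genes, percentile 90.1, Sdha at 0.22). Eef2, the toxin's target, stood at 304 FPKM in control and 279.8 in DTA.

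Few genes were lower at day 1, and of the 9 other than small RNA genes 1 stayed at -1 or less against the day 5 control. They include Rangrf (-3.63), Gpx3 (-3.26), Fmod (-1.86), Hfe (-1.25), Sned1 (-1.21), Fam107a (-1.06) and Col9a1 (-1.002). Gpx3, a secreted glutathione peroxidase, stood at 39.0 FPKM in the day 1 control, 3.17 in day 1 DTA and 3.60 in the day 5 control. Rangrf lies next to Slc25a35 with overlapping ends, so fragments there cannot be assigned with certainty. Over 2623 genes at 5 FPKM or more, 54 were higher and 16 lower in DTA, and without small RNA genes 34 and 9. The calls were 2.67% of these genes, and 2.57% between the 2 controls. These shares are not alike, since no rule on the controls applied to the controls and more of their calls were small RNA genes. Without small RNA genes, 10 were higher and 68 lower between the controls, over 9321 genes at 5 FPKM or more. Against the day 5 control 85 were higher and 10 lower, so that 89.5% of calls were higher in place of 77.1%, and against the mean of both controls 60 were higher and 7 lower (89.6%). With no requirement on the controls 70 were higher and 34 lower (67.3%), the lowest share of the settings tried.

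At day 5 the question is which transcripts differ once the injury has progressed. Most rod markers and some cone markers were lower in DTA than in control, and most genes of the reactive gliosis, interferon and microglia lists were higher. Gnat1, the rod transducin alpha subunit (chromosome 9, 107576805 to 107581923), stood at 6678 FPKM in control and 739 in DTA, 9.03-fold lower. Icam1, an adhesion molecule for leukocytes (chromosome 9, 20820404 to 20833240), stood at 0.164 FPKM in control and 88.5 in DTA, a difference of 6.27. Lcn2, an iron-binding acute phase protein of reactive astrocytes (chromosome 2, 32240157 to 32243259), stood at 3.10 and 116 FPKM, 37.3-fold higher. Lens transcripts were lower in DTA as well, though their median difference between the 2 controls was larger in size.

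The other genes with the largest positive differences at day 5 were Cxcl10 (5.19, listed at 0 in control), Steap4 (4.92), Ccl2 (4.91, listed at 0 in control), Maff (4.68), Serpina3n (4.66), Timp1 (4.50), Bcl3 (4.32) and Fgf2 (4.22). Steap4 is a metalloreductase induced by inflammation, Maff a small Maf transcription factor, Timp1 a metalloproteinase inhibitor and Bcl3 a partner of NF-kappa B. Fgf2, a survival factor for photoreceptors, stood at 3.57 and 84.0 FPKM. Its neighbour Nudt6, transcribed from the opposite strand, differed by 3.80, so the source of some fragments is open.

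Rod markers were lower as a list: 18 of 29 were called lower and none higher, with a median of -1.19 (percentile 0). After Gnat1 the largest differences were Reep6 (-3.08), the nuclear receptor Nr2e3 (-2.73) and the rod transcription factor Nrl (-2.34, from 779.9 to 153 FPKM). The differences were uneven across members. Sag stood at 1559 and 1444 FPKM, Pde6a differed by -0.21, and Rp1 and Aipl1 by 0.42 and 0.48. Of 15 cone markers 5 were lower and 1 higher (median -0.65, percentile 0). Opn1sw, the short wavelength opsin, stood at 195 and 17.9 FPKM, Opn1mw differed by -1.79 and Gnat2 by -1.69, while Gnb3 stood at 107 and 328.

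**Figure D1:**
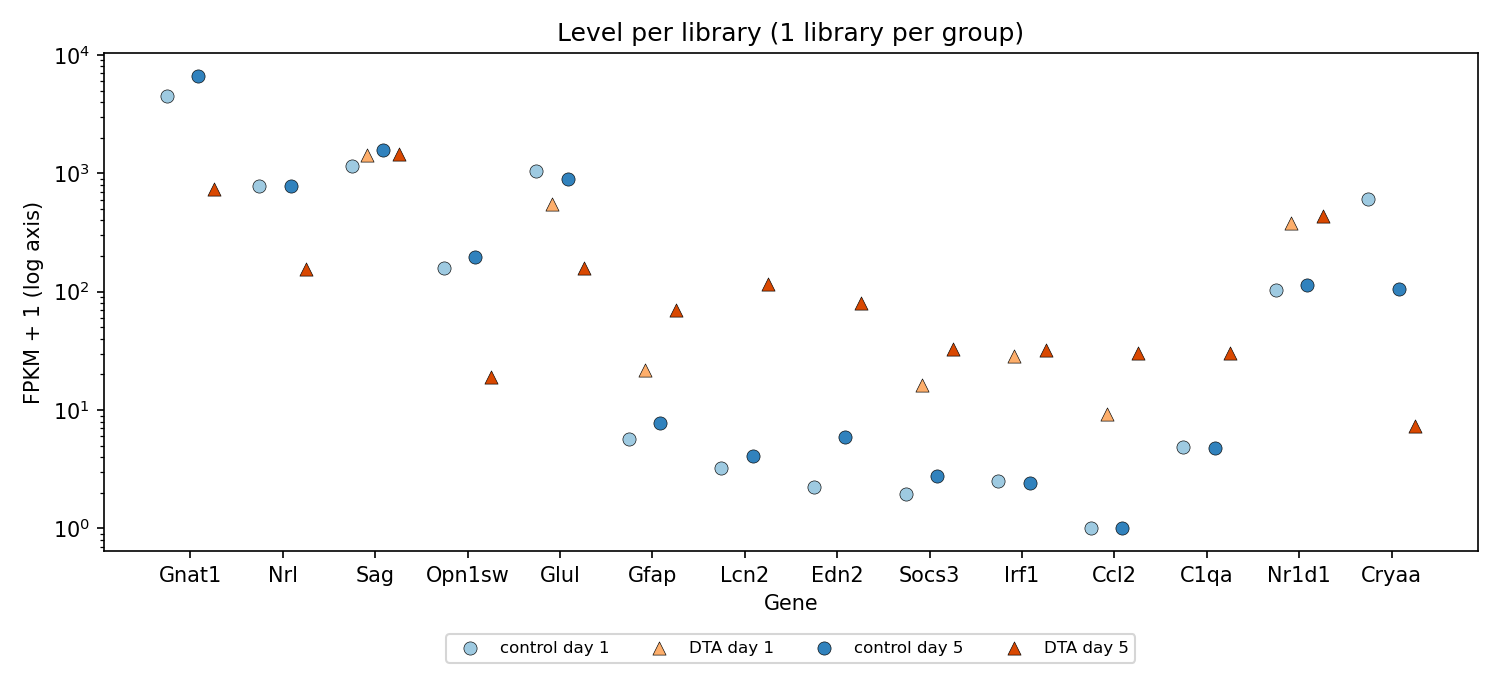
FPKM + 1 of selected genes in the 4 libraries, on a log axis with 1 point per library and no error bars since each group has 1 library. Points missing for day 1 DTA are genes outside the part of the genome its file covers; Gnat1 stands at 6678 FPKM in the day 5 control and 739 in day 5 DTA, and Gfap at 6.85 and 68.5.

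Of 17 Müller glia markers 3 were lower and 1 higher (median -0.30, percentile 0). Between the 2 controls the same markers had a median of -0.38 (day 5 minus day 1), larger in size than this list median. Spc25 differed by -3.10, Glul stood at 888 and 159 FPKM, and Rlbp1, the retinaldehyde binding protein, differed by -1.41. Vim, the intermediate filament vimentin, was higher (1.20), a call that ended under median ratio scaling (0.95) and against the day 1 control (0.78). Inner retinal lists had no call: bipolar (14 measured, median -0.09, percentile 0.66, Scgn at -0.47), amacrine (9, -0.33, percentile 0.12, Slc18a3 at -0.58), horizontal (7, -0.42, percentile 0.06, Sept4 at -0.83) and ganglion cells (13, -0.11, percentile 0.88, Pou4f3 at -0.62). The ganglion cell median was 0.0178 against the day 1 control.

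Reactive gliosis genes had the highest median of all lists at day 5. Of 20 measured, 16 were higher and none lower, with a median of 3.18 (percentile 100). Gfap stood at 6.85 and 68.5 FPKM, a difference of 3.15. Of 20 interleukin-6 family and survival factor genes 6 were higher (median 0.71, percentile 100), among them Edn2, Fgf2 and Socs3, which also stand in the reactive gliosis list. Edn2, endothelin 2, stood at 4.88 and 79.4 FPKM, 16.3-fold higher, Socs3 differed by 3.58, and Lif stood at 0.248 and 5.87 FPKM.

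Microglial, phagocyte, complement, chemokine and interferon genes were higher as lists. Of 21 microglia and macrophage markers 13 were higher and none lower (median 1.61, percentile 100), with Lyz2 at 2.88, Fcer1g at 2.73, Aif1 at 2.72 and C1qa at 2.67. Among those not called were Tmem119 (0.68), P2ry13 (0.65), P2ry12 (0.17) and Siglech (-0.15), each under the floor of 5 FPKM. The list does not separate microglia from macrophages. Of 18 activated phagocyte genes 5 were higher (median 1.11, percentile 100), among them Lgals3 (2.54) and Gpnmb (1.72, but 0.89 with a pseudocount of 5). Of 17 complement genes 7 were higher (median 1.31, percentile 100), led by C3 (3.14). C1qa, C1qb and C1qc, among these 7, also stand in the microglia and macrophage list. Of 23 chemokines and cytokines 7 were higher (median 0.81, percentile 100), with Ccl5 at 4.17 and Cxcl1 at 3.98. Of 30 interferon and antigen presentation genes 20 were higher (median 2.04, percentile 100), with Irf1 at 3.73, Bst2 at 3.34 and Tap1 at 2.87. None of 14 markers of other leukocytes was called (median 0.05, percentile 93.4), with Ly6c2 at 0.35.

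Stress lists differed in how many members were called. Of 21 p53 and cell death genes 8 were higher (median 0.88, percentile 100): Cdkn1a, the cell cycle inhibitor p21, stood at 3.65 and 50.8 FPKM, and Fas and Phlda3 differed by 2.43 and 2.14. Of 20 integrated stress response genes 5 were higher (median 0.52, percentile 99.7), with Atf3 at 3.20, Nupr1 at 2.40 and Atf4, the response's transcription factor, at 105 and 515 FPKM. Of 21 immediate early genes 9 were higher (median 1.47, percentile 100), with Egr1 at 3.94, Junb at 3.48 and Jun at 2.79. Egr1 stood at 36.0 FPKM in the day 1 control. Of 14 heat shock and oxidative stress genes 3 were higher (median 0.30, percentile 73.6): the metallothioneins Mt2 (2.53) and Mt1 (1.79), and heme oxygenase Hmox1 (2.45). Of 14 clock genes 3 were higher (median 0.78, percentile 100): Nr1d1 (1.95), Bhlhe41 (1.51) and Cry1 (1.39).

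Proliferation and progenitor genes had few calls. None of 22 cell cycle genes was called (median 0.57, percentile 99.98), with 21 above 0 and Ccnb2 at 1.55, Mcm6 at 1.43 and Birc5 at 1.33, each under the floor of 5 FPKM. Of 22 progenitor and neurogenic factors 1, Neurod1 (1.11), was higher (median -0.03, percentile 0.8), a call that ended under median ratio scaling (0.87), under the sum without photoreceptor and abundant genes (0.92) and against the day 1 control (0.92). Msi1 stood at 90.0 and 47.9 FPKM, a difference of -0.89. Of 20 matrix genes 5 were higher (median 0.25, percentile 79.4), with Cyr61 at 2.17, Tgm2 at 1.66 and Col4a1 at 1.33 (0.88 with a pseudocount of 5). Of 10 EGF receptor ligands and receptors 1, betacellulin (Btc, 1.71), was higher (median 0.21, percentile 73.6). None of 7 diphtheria toxin target pathway genes was called (median 0.35, percentile 75.6), and Eef2 stood at 369 and 339 FPKM. Of 14 housekeeping genes 2, B2m (2.54, also in the interferon list) and Gusb (1.23, but 0.69 with a pseudocount of 5), were higher (median 0.37, percentile 97.2).

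Lens and pigment epithelium markers differed between DTA and control as well. Of 19 lens markers 8 were lower (median -2.50, percentile 0), and 7 of them stood among the 10 genes with the largest negative differences: Cryaa (-3.85), Crygc (-3.83), Crybb2 (-3.80), Cryba1 (-3.71), Cryba2 (-3.55), Crygb (-3.44) and Crygs (-3.22). Beside Gnat1 and Opn1sw the remaining one was Ccdc24 (-3.39), at 66.5 and 5.43 FPKM. Between the 2 controls the lens median was -2.85 (day 5 minus day 1), larger in size than between DTA and control. Crygb differed by -3.41 and Crygs by -2.97 between the controls, close to their day 5 differences. The 13 pigment epithelium markers had a median of -0.31 (percentile 0), no call, and Rpe65 stood at 2.69 and 0.516 FPKM. The 5 red blood cell markers had a median of 0.31 (percentile 80.0), the 12 endothelial markers 0.09 (percentile 15.4, a sign that turned to -0.07 under median ratio scaling and to -0.03 under the sum without photoreceptor and abundant genes) and the 13 markers of cornea, iris, muscle and connective tissue 0.11 (percentile 82.8), none with a call. Against the day 1 control the red blood cell median was -0.24 and that of cornea, iris, muscle and connective tissue -0.0222. Vwf stood at 0.78 and Hbb-b1 at 1.35.

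**Figure D2:**
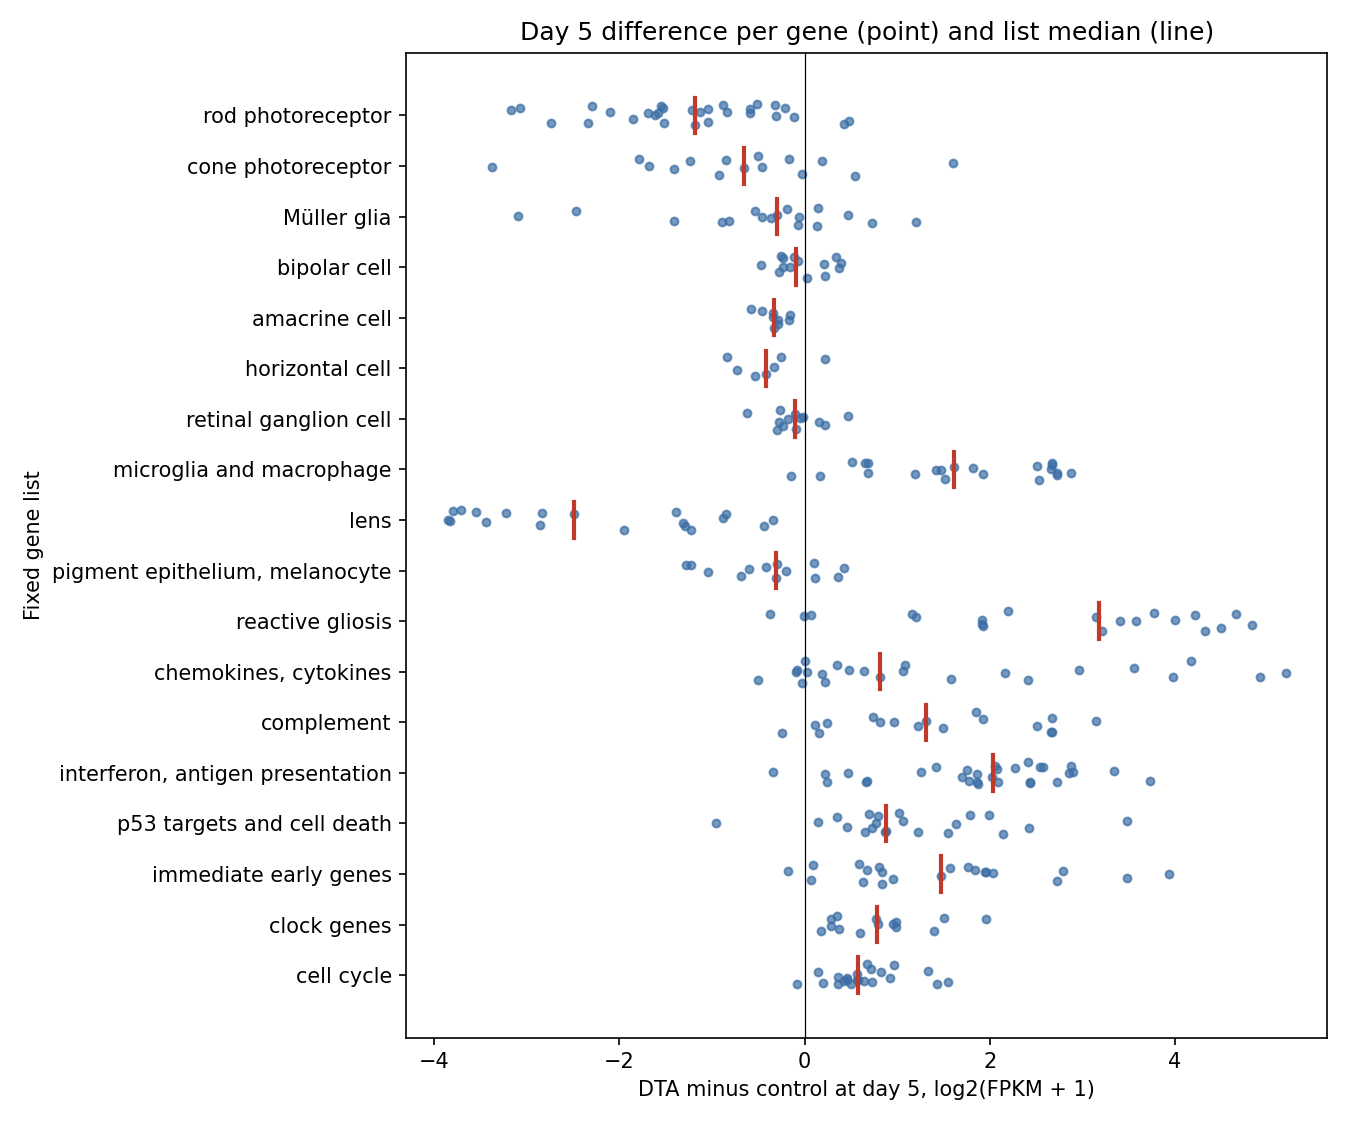
Differences of log2(FPKM + 1), DTA minus control at day 5, of the members of selected fixed gene lists, with 1 point per gene and a bar at the list's median. The medians run from -2.50 for lens markers to 3.18 for reactive gliosis genes.

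Over 9895 genes at 5 FPKM or more, 667 were higher and 175 lower in DTA at day 5, so that 79.2% of calls were higher, and without small RNA genes 577 and 133. The calls were 8.51% of these genes, against 2.57% between the 2 controls, where no rule on the controls applied. The median difference of all these genes was 0.26 as deposited and 0.04 after scaling by the median ratio, under which 424 were higher and 255 lower (62.4% higher). Scaling to the same sum without photoreceptor markers and the most abundant genes gave a median of 0.09 with 463 higher and 235 lower (66.3% higher). List medians can be read against these shifts.

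The difference between the 2 days can be read for the 2777 genes at 5 FPKM or more that the day 1 DTA file also holds. Of genes called higher at day 1, most were called higher again at day 5. Among 2662 such genes other than small RNA genes, 33 were higher at day 1, 144 at day 5 and 22 at both, against 1.79 shared by chance if the calls were independent. The 22 include Gadd45b, Irf1, Ccl2, Ccl5, Socs3, Serpina3n, Gfap, Fos, Atf3 and Nr1d1. All 33 had a day 5 difference above 0. Lower at both days were 2 genes, among them Fam107a, of 9 and 43, against 0.145 if independent. None was called in opposite directions, against 0.533 and 0.487 if independent, so this says little. Rangrf, Crygb, Crygc and Crygd passed the size and floor in opposite directions, but none met the rule on the controls at both days. That rule uses the same control difference at both days, so the calls are not fully independent.

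**Figure D3:**
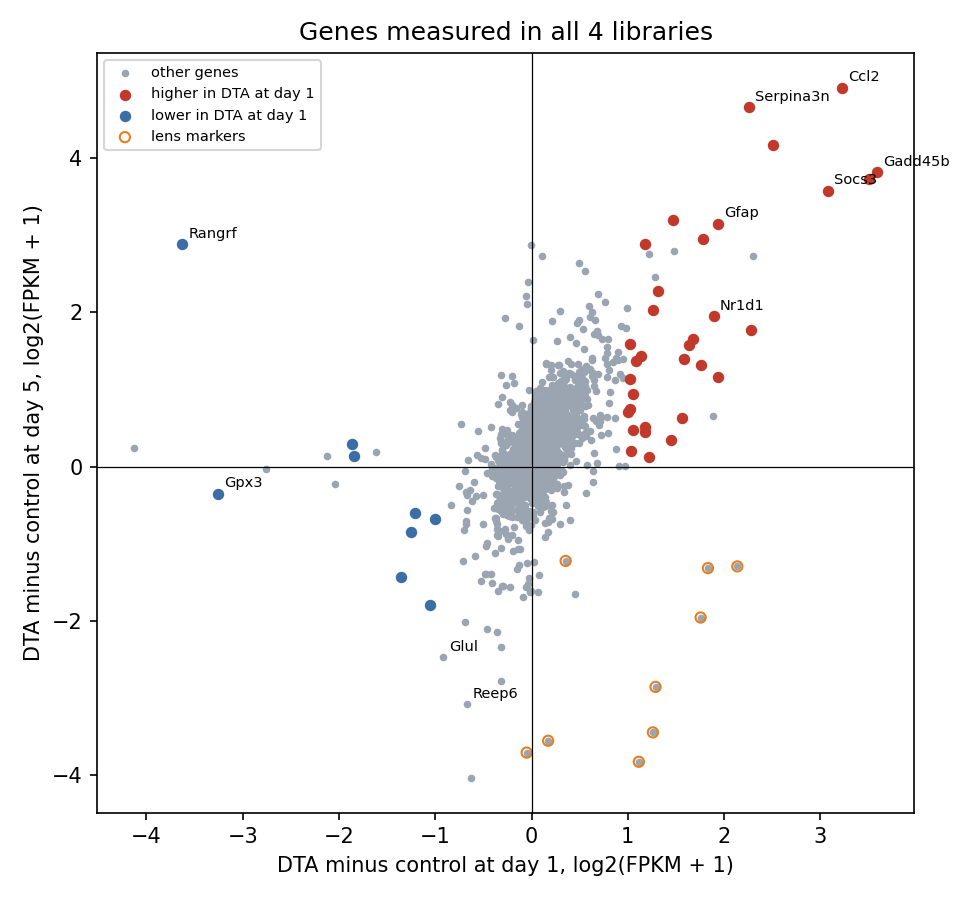
Differences of log2(FPKM + 1), DTA minus control, at day 1 on the horizontal axis and day 5 on the vertical axis, with 1 point for each of 2662 genes. Of the 33 genes higher at day 1, all lie above 0 at day 5, and the lens markers lie above 0 or near it at day 1 and below 0 at day 5.

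Genes whose difference was larger at day 5 than at day 1 were led by Rangrf (6.51), Optc (4.36), the microglia and macrophage markers Lyz2 (2.88) and Fcer1g (2.62) and Chi3l1 (2.44), a chitinase-like protein of reactive glia. Rangrf differed by -3.48 between the controls, more in size than its day 5 difference of 2.88, which was not called. Lyz2 stood at 1.09 and 1.08 FPKM at day 1 and at 0.269 and 8.32 at day 5. Optc, opticin of the vitreous, stood at 33.5 FPKM in the day 1 control and between 0.795 and 1.11 in the other libraries, so its difference rests on the day 1 control. Those in the other direction were crystallins: Crygc (-4.94), Crygb (-4.71), Crygd (-4.14), Cryba2 (-3.73) and Cryba1 (-3.66). Gfap was higher by 1.21 more at day 5 than at day 1, Glul lower by a further -1.55 and Reep6 by a further -2.40. In all, 84 genes had a difference larger by at least 1 at day 5 and 70 a difference smaller by at least 1, of which 59 and 38 were not small RNA genes. These are differences between 4 single libraries and were not tested.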

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

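All tests in this part were chosen after the result was seen. Results were picked out here because the difference between DTA and control had opposite directions at day 1 and day 5; the change between days was not tested, since each group has 1 library. Crygb differed by -4.71 (day 5 difference minus day 1 difference), Crygc by -4.94 and Crygd by -4.14, and the median of the lens list by -3.68, from 19 markers at day 5 and the 10 measured at day 1. Rangrf differed by 6.51. These values rest in part on the controls, in which Crygb differed by -3.41, Crygc by -3.50, Crygd by -3.73, the lens list by a median of -2.85 and Rangrf by -3.48 (day 5 minus day 1). For Rangrf that is larger in size than its day 5 difference of 2.88, which was not called, and against the day 5 control its day 1 difference was -0.15.

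Of 9 genes called lower in day 1 DTA other than small RNA genes, 1 stayed at a difference of -1 or less when day 1 DTA was set against the day 5 control, with a median of -0.15 in place of -1.35. This is in line with the day 1 control library standing apart from the other 3 for these genes. Lens tissue carried along in that control is argued against, since the 10 lens markers had a median of 1.19 in the other direction (SD over genes 0.813). The 3 measured pigment epithelium markers were lower as well, with a median of -0.71 (SD over genes 0.162, lowest -0.95). This cannot decide whether pigment epithelium carried along is the cause. How far such tissue moves a gene depends on the gene's level in both tissues, which was not measured. Tissue without a fixed list here and a difference between the mice of the day 1 control also stay open and were not tested. That control also differed from the day 5 control in sex-linked transcripts.

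Rod transcripts differed unevenly at day 5, where the 29 rod markers ranged from -3.17 to 0.48. If rods alone were lost, each rod transcript should fall by about the same share, but the SD over the markers was 0.945 against 0.286 between the controls. Transcript length is not the whole cause either: after a straight line on log2 length was taken out (0.31 per doubling), the SD was 0.920. A lower output of some rod genes in remaining rods, Gnat1, Reep6, Nr2e3 and Nrl among them, may add to a loss of rods and was not tested further.

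The clock list had a median of 0.85 at day 1 and 0.78 at day 5. A lower share of rods, which would raise all other transcripts, is argued against at day 1 by a rod median of 0.0381. At day 5 the 43 bipolar, amacrine, horizontal and ganglion cell markers had a median of -0.235 (SD over genes 0.301). This cannot decide the question, since those transcripts may themselves be lower in DTA. The median of all genes at 5 FPKM or more was 0.26 at day 5, so a general shift may make up part of the clock median. Collection at another time of day than the controls stays open: relative to the median of all genes at day 5, Arntl stood at 0.529, Clock at -0.0859 and Npas2 at 0.0845, where a shift in phase should place these apart from Nr1d1, while at day 1 Npas2, the one of them in that file, differed by 0.85 in the direction of Nr1d1, from 0.685 to 2.03 FPKM and so under the floor. Injury and time of collection cannot be told apart here, since the labels give no hour.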

How the results depend on the processing

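Added after the data were seen were the settings that read failed estimates as 0, leave out small RNA genes, leave out lens and pigment epithelium markers, use only genes of the day 1 file, or take list members at 5 FPKM or more. Of 79 counts under other settings 63 lay within 1.5 times the main count, and no named gene's call turned to the other sign. The count of genes higher at day 1 (54) was 35 with a pseudocount of 5, 34 with a floor of 10 FPKM, 85 against the day 5 control and 34 without small RNA genes. The count lower at day 1 (16) was 10 with a floor of 10 FPKM, 10 with intervals that do not overlap, 10 against the day 5 control, 7 against the mean of both controls, 34 with no requirement on the controls and 9 without small RNA genes. At day 5 the count higher (667) was 350 with a pseudocount of 5, 424 under median ratio scaling and 173 on the genes of the day 1 file alone, and the count lower (175) was 60 on those genes. The count differing between controls (240) was 95 with intervals that do not overlap and 78 without small RNA genes. Fewer genes explain the counts on the day 1 file and without small RNA genes; for the others the cause was not tested. Full ranges were 34 to 85, 7 to 34, 173 to 928, 60 to 255 and 78 to 296. The median of pigment epithelium markers at day 1 was 1.03 against the day 5 control (main -0.71) and that of ganglion cell markers at day 5 was 0.0178 against the day 1 control (main -0.11). Of 458 medians of lists of at least 3 measured genes under other settings 258 moved by no more than the list's median difference between the controls, and 18 had the other sign, the pair just given among them. The 258 include 24 of 55 against the control of the other day. There the change stems from the same control difference, so it is no measure of stability. Of 1344 differences of named genes 983 moved by no more than the gene's difference between the controls. For the 224 of the 1344 against the control of the other day, the change is that control difference itself, so they show no stability. In all, 45 of the 1344 had the other sign, none of them of a called gene. Against the day 5 control these include, at day 1, Isl1 (0.31), Six6 (0.15), Rgr (1.45), Rgs5 (-0.28) and Sag (-0.14), and against the day 1 control, at day 5, Hbb-b1 (-0.10) and Eef2 (0.16). No paired analysis was possible within a day because each group is a single library; a fit of DTA over both days with day as a block, on the genes in all 4 files with 1 residual degree of freedom, was not made. Depth limits the low end: a fragment on 1 kilobase is worth up to 0.0348 FPKM.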

Other observations

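The genes in this part were chosen after their values were seen, and no test was made on them. They are single genes, and nothing is said of the other members of their pathways. Relb, an NF-kappa B subunit of the non-canonical pathway, stood at 0.907 FPKM in the day 5 control and 19.0 in day 5 DTA, a difference of 3.39, and at the same day Nfkb2 differed by 2.98, Birc3 by 2.59 and Nfkbie by 2.25. Of acute phase genes, Ptx3 differed by 3.93 and Saa3 was listed at 0 in control and at 11.6 FPKM in DTA. Irgm1, an interferon-inducible GTPase, differed by 1.78 at day 1 and 2.95 at day 5, and Igtp, another, by 1.18 and 2.89. Vcam1, an adhesion molecule like Icam1, differed by 1.88 at day 5.

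A few genes known from photoreceptors that stand outside the fixed lists were lower in DTA at day 5. Nxnl1, which encodes a cone survival factor, differed by -2.01, Pitpnm3 by -2.02, Impdh1 by -1.32, Cdhr1 by -1.15 and Kcnv2, a potassium channel subunit of photoreceptors, by -1.08. The transcription factors Mef2c and Esrrb, which are also active in rods, differed by -2.10 and -1.63.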
